A study of Homo sapiens with 3 samples.

How the data were processed

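RNA of DV90 cells was measured by mRNA sequencing in 3 libraries, 1 with control siRNA and 2 with REG4 siRNA. RNA was extracted with Trizol and polyadenylated RNA was sequenced, per the labels. HISAT2, featureCounts and the build hg38 are named in the submitters' processing notes, without versions, and the annotation, the strand setting and the treatment of reads matching several genes are not given in the sources used here. The authors deposited 1 table of FPKM values for 41768 genes, per the file headers, with a gene name and a gene type for each row. FPKM divides reads by gene length and by a library total, so a large change of a few abundant genes shifts all others, and reads shared by near-identical genes or by a small RNA and its host gene can be assigned to either. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart.

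The deposited FPKM held whole reads. Short RNA genes, whose length is known from RefSeq, gave the library total as the commonest value of 1 read, and FPKM times that total then gave reads and gene length in lowest terms. The 3 values came out whole, within 1e-06 reads, for 24156 of 24157 genes above 0 (99.996%). The recovered reads are lower bounds where a common divisor was lost, and they summed to between 95.5% and 95.6% of the totals. In simulated tables of 5912 genes with reads above 0, the reads were exact for 90.7% and exact up to a common divisor for 100%. Totals of 12263137 to 12905627 reads mean that genes at 1 FPKM rest on few reads, and short RNA genes on fewer still. Exact 95% intervals of read ratios used the binomial distribution and cover counting error only. A gene with 0 reads allows up to 3 counts in a library, so no fold change was given against 0 reads.

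Values were analysed as log2(FPKM + 1) for genes with a mean FPKM of at least 1 over the 3 libraries, with R 4.3.3 and limma 3.58.1 (lmFit, then eBayes with a trend) and Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. Tests were two-sided. No count model was used for the main result because the unit is FPKM. Gene lists, 39 in number, were tested with limma's camera on the same values, with an inter-gene correlation preset at 0.01, for the 34 lists with at least 5 measured genes, and again with the correlation estimated. With the correlation estimated, camera rests on the 1 residual degree of freedom of the fit, which leaves it little power. For each library, the median of a list was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Genes at least 2-fold from the control in both libraries were counted without a test. Because both log2 ratios share the control, 200 sets of unchanged libraries were simulated, from the limma spread per gene and separately as reads.

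The named genes were REG4, then the 12 higher and 12 lower genes with the largest smaller-of-both absolute log2 ratio among those with the same sign in both libraries, taken first from genes called by limma and then from genes at least 2-fold in both, and up to 4 members of each list with the largest mean change. The design, lists, naming rule and most alternatives were fixed before the data were examined. Since the rule selected mostly genes with few reads, genes ranked in the same way among those with at least 100 reads were named as well, and these, the genes of the comparison between the REG4 siRNA libraries and the alternatives with a read minimum, voom or a GC correction were chosen after their values were seen. GC content was that of the longest GENCODE v29 transcript of a gene, and the correction subtracted a loess fit (span 0.3) of each library's deviation from the gene mean. Gene coordinates are those of GENCODE v29 on GRCh38. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for reading the table.

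The scripts were tested on simulated reads for the comparison of REG4 siRNA with control, with 200 changed genes. Over 13331 genes, limma called 56.1% of genes changed 2-fold and 93.8% of genes changed 4-fold, and 33 unchanged genes. Over 11959 genes with at least 100 reads, it called 100% of genes changed 2-fold and 100% of genes changed 4-fold, and 50 unchanged genes, so calls at this design size include more unchanged genes than the threshold states. The simulated spread per library had an SD of 0.085 on the log2 scale, taken from well-covered genes. Camera called the 1 list that was shifted in simulation and 0 others. Alternatives tried were other pseudocounts, scalings, filters and fold thresholds, other settings of limma and camera, and leaving out each REG4 siRNA library.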

Results

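Polyadenylated RNA of DV90 cells, a human lung adenocarcinoma line, was sequenced after transfection with a control siRNA or with siRNA against REG4. REG4 encodes a secreted lectin of the regenerating family that is found mainly in the gastrointestinal tract and in mucinous tumours. The data comprised 1 control siRNA library and 2 REG4 siRNA libraries, numbered 1 and 2. The labels do not say whether these numbers stand for different siRNAs or for repeat cultures. P-values of single genes thus measure only the spread between these libraries, which may be technical. Camera's p-values with a preset correlation compare genes with genes and do not measure that spread. The FPKM values implied totals of 12669942 reads for the control library, 12263137 for REG4 siRNA library 1 and 12905627 for REG4 siRNA library 2. A mean FPKM of at least 1 was reached by 13530 genes. All log2 ratios below are against the control library on the log2(FPKM + 1) scale, which understates changes of genes with low values.

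The first comparison was of the targeted gene. REG4 lies on chromosome 1 from 119794018 to 119811660 on the minus strand of GRCh38 (ENSG00000134193.14). Its level was 485 FPKM in the control library, 204 FPKM in REG4 siRNA library 1 and 89.4 FPKM in REG4 siRNA library 2, a mean of 147 ± 81.0 FPKM (SD, n = 2) with REG4 siRNA. REG4 was thus at 42.1% of the control level in library 1 and at 18.4% in library 2. These values rested on 9316, 3795 and 1750 reads, and the exact 95% intervals of the read ratio to the control were 0.405 to 0.437 and 0.175 to 0.194, which cover counting error only. The log2 ratios were -1.24 and -2.43, with a mean of -1.84 ± 0.84 (SD, n = 2). REG4 did not pass the planned test across all genes (limma, standard error 0.48, adjusted p = 0.809), although both libraries lay below the control. Of the REG family, REG4 was the only member with a mean FPKM of at least 1, and with the p-value adjusted over the list alone it was the 1 gene called.

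**Figure D1:**
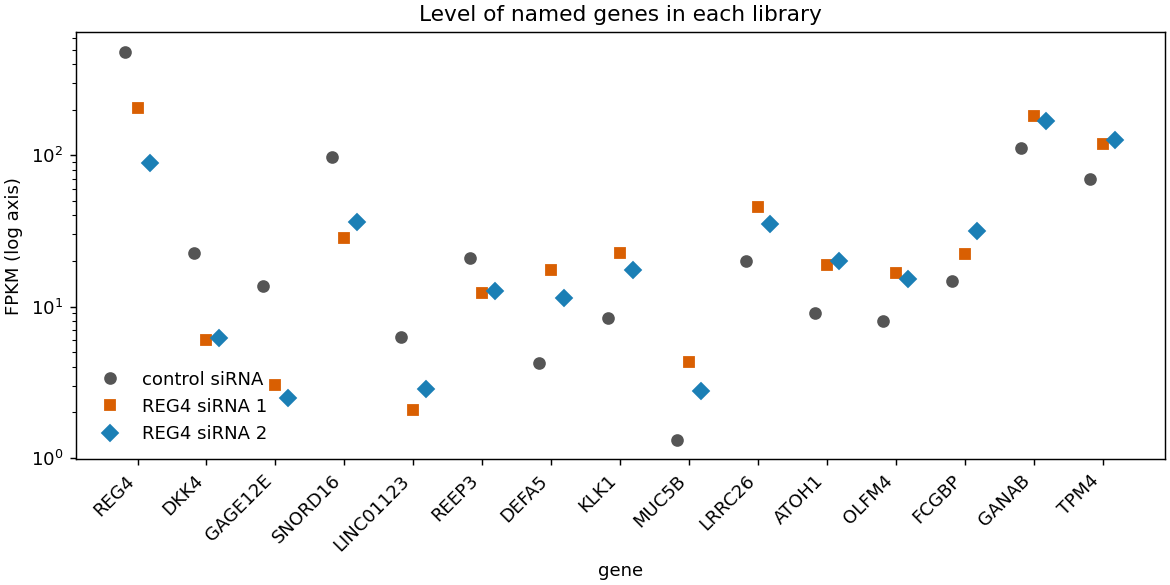
FPKM (log axis) of 15 genes in the control siRNA library (grey circles) and in REG4 siRNA libraries 1 (orange squares) and 2 (blue diamonds), each point being 1 library. REG4 was at 485, 204 and 89.4 FPKM, and DKK4, GAGE12E, SNORD16, LINC01123 and REEP3 were also below the control in both libraries, while the other genes were above it.

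The second comparison asked which other genes differed from the control in both REG4 siRNA libraries. Among genes with higher values in both was ATOH1, a transcription factor that specifies secretory cells of the gut, at 9.12 FPKM in the control and at 18.8 and 19.9 FPKM in the REG4 siRNA libraries. DEFA5, an antimicrobial defensin of Paneth cells, was at 4.22, 17.4 and 11.4 FPKM, from 24, 96 and 66 reads. The gel-forming mucin MUC5B (1.32, 4.31 and 2.76 FPKM), the mucus protein FCGBP (14.8, 22.2 and 31.4 FPKM), the kallikrein KLK1 (8.38, 22.5 and 17.4 FPKM) and the secreted glycoprotein OLFM4 (8.08, 16.7 and 15.3 FPKM) were also higher in both libraries. So were SPDEF, a goblet cell transcription factor, with log2 ratios of 0.71 and 0.62, and the actin-binding tropomyosin TPM4, with 0.75 and 0.83. Among genes with lower values, DKK4, a secreted WNT inhibitor, was at 22.6 FPKM in the control and at 5.98 and 6.16 FPKM with REG4 siRNA. The lncRNAs LINC01123 (log2 ratios of -1.25 and -0.94) and UCA1 (-1.05 and -0.77) were lower in both libraries, as were REEP3, a protein of the endoplasmic reticulum (-0.72 and -0.67), and TFRC, the transferrin receptor (-0.50 and -0.40). Low values were also found for the cancer-testis gene GAGE12E (-1.85 and -2.07) and for SNORD16 (-1.73 and -1.39). GAGE12E has near-identical copies and SNORD16 lies inside RPL4, so their reads could have been shared and both are uncertain.

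None of these genes passed the planned test. With limma on 13530 genes, 0 genes had an adjusted p under 0.05, the smallest adjusted p being 0.189, while 777 genes had an unadjusted p under 0.05, of which 518 were higher and 259 lower. The fit had 1 residual degree of freedom, from the difference between the 2 REG4 siRNA libraries, and the lone control was assumed to vary as they do. Restricting the genes to the 11994 with at least 100 reads summed over the libraries, a choice made after the data were seen, gave 5 called genes with limma, of which ATOH1 and TPM4 rose (adjusted p = 0.0483 for each) and DKK4, GAGE12E and SNORD16 fell. On the reads recovered for the same genes, limma's voom called 15 genes at an adjusted p under 0.05, without ATOH1 (voom adjusted p = 0.0628). Of these, 9 rose, among them TPM4 (log2 ratio 0.80, adjusted p = 0.00259), KLK1 (1.23, adjusted p = 0.0223), MUC5B (1.38, adjusted p = 0.0223) and FCGBP (0.84, adjusted p = 0.0284), each higher in 2 of 2 libraries. The 6 that fell included REG4 (-1.85, adjusted p = 0.00497), DKK4 (-1.89, adjusted p = 0.00259) and REEP3 (-0.74, adjusted p = 0.0169) in voom, each lower in 2 of 2 libraries. The same sign in both libraries is no separate check, since both share the control and the genes were called on both together. Voom was not run on simulated reads or on other groupings of the libraries.

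By the rule of size fixed in advance, 48 genes were at least 2-fold higher in both libraries, 32 were at least 2-fold lower and 4 passed 2-fold in opposite directions. Most of them were genes of types other than mRNA, namely 46 of the 48 and 28 of the 32. Under 100 recovered reads in all were found for 47 of the 48 and 28 of the 32. The medians over the 48 and the 32 were 6 and 7 recovered reads. The 12 higher genes that the naming rule selected were all of types other than mRNA, with 2 to 28 recovered reads. In the control, 10 of them had 0 reads. Recovered reads are lower bounds where a common divisor was lost, as the recovered length of 30 for the lncRNA LOC102723738 shows. They included TRNAC3 with 0, 9 and 5 reads and MIR6802 with 3, 12 and 13 reads. Of the 12 lower genes, 10 were of types other than mRNA with under 100 reads, such as SNORD1C with 20, 3 and 3 reads, and the others were DKK4 and GAGE12E. Unchanged libraries sharing a control, simulated as reads, gave a mean of 35.2 higher genes (95% of draws between 23 and 46) and 22.9 lower genes (15 to 32). Those simulated from the limma spread gave 7.89 (3 to 13) and 8.19 (3 to 13). The simulation of reads drew from the recovered reads, so it overstates counting error for genes that lost a common divisor. Even so, it gave a mean of 146 genes at least 2-fold apart between the REG4 siRNA libraries, where 239 were observed. Independent lists of the observed sizes would have shared 1.04 and 0.994 genes. With at least 100 reads, DEFA5 was the 1 gene at least 2-fold higher, and REG4, DKK4, GAGE12E and SNORD16 were the 4 at least 2-fold lower, where both simulations gave means under 1 gene for each direction. These simulations understate the spread, since they gave means of 0.790 and 0.220 genes at least 2-fold apart between the REG4 siRNA libraries, where 17 were observed. The pseudocount of 1 lowers such counts, and plain FPKM ratios gave 15 genes higher, ATOH1, KLK1 and MUC5B among them, and 7 lower. At 1.5-fold, 38 of these genes were higher, 13 were lower and 2 passed in opposite directions.

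**Figure D2:**
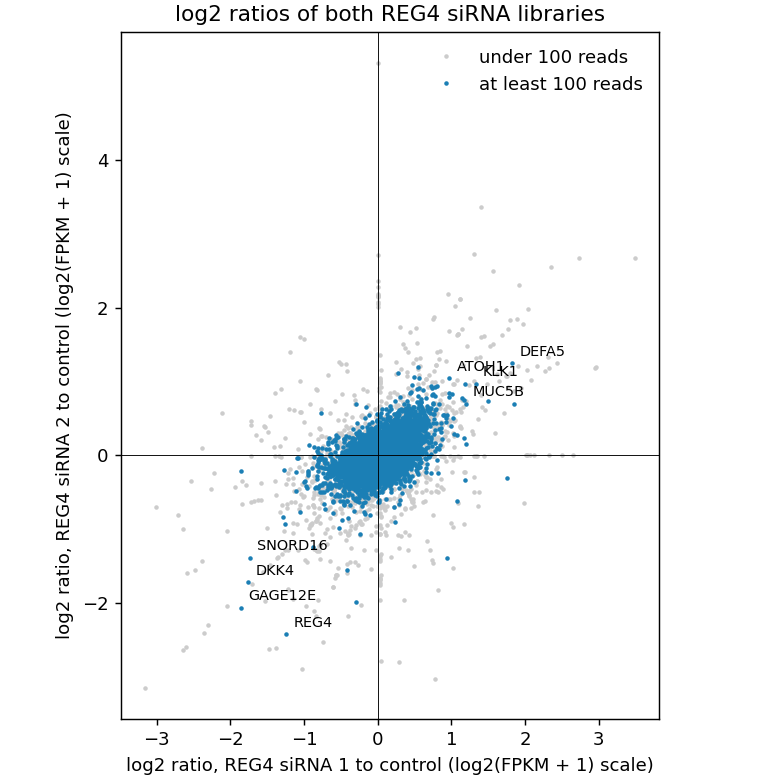
Log2 ratio to the control library on the log2(FPKM + 1) scale in REG4 siRNA library 1 (x axis) and library 2 (y axis), with 1 point per gene, in grey for genes with under 100 reads and in blue for the others. REG4, DKK4, GAGE12E and SNORD16 lie at the lower left, and DEFA5, KLK1, ATOH1 and MUC5B at the upper right.

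The log2 ratios of the 2 REG4 siRNA libraries were correlated across the 13530 genes (Pearson r = 0.515, Spearman rho = 0.554), genes not being independent replicates. Simulated unchanged libraries that share the control gave a mean r of 0.501 and a mean rho of 0.470. The covariance was 0.0523, against 0.0243 in the simulation from the limma spread and 0.0323 in the simulation of reads. The variance of the difference between the REG4 siRNA libraries divided by 2, which is the covariance that a control library varying as they do would give, was 0.0495. This lies close to the observed covariance, so the shared control may account for most of it. The control could not be split to test this.

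The third comparison was of gene lists fixed before the data were examined. Of 34 lists with at least 5 measured genes, camera called 5, all of them higher with REG4 siRNA, at an adjusted p under 0.05 with a preset correlation. In that setting genes rather than libraries act as the replicates. None of these calls held with an estimated correlation, where the smallest camera adjusted p was 0.835. Camera then rests on the 1 residual degree of freedom of the fit, so it had little power to call any list. The estimated correlation was negative for immediate early (-0.067), mesenchymal (-0.111) and YAP genes (-0.026). It was positive for mucins and trefoil factors (0.077) and ribosomal proteins (0.232). With 1 residual degree of freedom, this estimate depends only on how many members were higher in library 2 than in library 1. It therefore cannot show whether the genes of a list vary together. Of the mucins and trefoil factors, 8 of 13 measured genes were higher in both libraries and 1 was lower (camera adjusted p = 0.0228, and adjusted p = 0.835 with an estimated correlation). The list's median log2 ratio was 0.12 in library 1 and 0.22 in library 2, at percentiles 89.1 and 100 among random lists matched on expression. TFF3, a trefoil peptide of goblet cells, had log2 ratios of 0.58 and 0.76 and was the 1 gene called by limma with p-values adjusted over the list alone, while 0 genes of the list were called over all genes. The gastric mucin MUC5AC had log2 ratios of 0.54 and 0.48. AGR2, which assists mucin folding, had 0.12 and 0.22.

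Ribosomal proteins had values higher in both libraries for 49 of 71 genes and lower for 3, with medians of 0.13 and 0.05 (camera adjusted p = 0.0228, and adjusted p = 0.835 with an estimated correlation). RPL28 had log2 ratios of 0.38 and 0.31. Immediate early genes, which respond first to growth factors and stress, were higher in both libraries for 12 of 15 genes and lower for 0, with medians of 0.18 and 0.10 (camera adjusted p = 0.0228, and adjusted p = 0.835 with an estimated correlation). IER2 (0.35 and 0.39), ATF3 (0.36 and 0.36) and JUN (0.35 and 0.31) were examples. Mesenchymal genes were higher in both libraries for 6 of 9 genes and lower for 0, with medians of 0.26 and 0.21 (camera adjusted p = 0.0228, and adjusted p = 0.835 with an estimated correlation). The contractile genes TAGLN (0.76 and 0.49) and ACTA2 (0.36 and 0.69) had the largest mean log2 ratios of that list. TAGLN was at 1.17 FPKM in the control and at 2.67 and 2.04 FPKM with REG4 siRNA, from 23, 51 and 41 reads. ACTA2 rested on 91, 119 and 164 reads. Only 9 of the 22 listed mesenchymal genes had a mean FPKM of at least 1. YAP targets were higher in both libraries for 9 of 13 genes and lower for 1, with medians of 0.22 and 0.16 (camera adjusted p = 0.0460, and adjusted p = 0.835 with an estimated correlation), among them CTGF (0.39 and 0.74) and CYR61 (0.30 and 0.29), secreted matricellular proteins. In none of these 4 lists was a gene called by limma, over all genes or adjusted over the list alone.

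The remaining 29 tested lists were not called by camera. Counts of list members with the same sign in both libraries are given without the share over all genes. Since both log2 ratios share the control, many unchanged genes would also have the same sign. Lysosome and autophagy genes were higher in both libraries for 16 of 25 genes and lower for 2 (camera adjusted p = 0.0519), and genes of the unfolded protein response for 14 of 19 and lower for 2 (camera adjusted p = 0.148). Apoptosis regulators were higher in both libraries for 12 of 20 genes and lower for 3 (camera adjusted p = 0.101), with log2 ratios of 0.62 and 0.41 for the BH3-only gene BBC3. Replication genes of G1/S were lower in both libraries for 16 of 28 genes and higher for 4 (camera adjusted p = 0.109) and mitotic genes of G2/M lower for 15 of 27 and higher for 8 (camera adjusted p = 0.105). NRF2 targets were lower in both libraries for 10 of 21 genes and higher for 3 (camera adjusted p = 0.109), with -0.95 and -0.21 for the cystine transporter SLC7A11. Glycolysis genes were lower in both libraries for 9 of 15 and higher for 3 (camera adjusted p = 0.386), and LDHA, which converts pyruvate to lactate, had -0.36 and -0.33. ERK pathway output was lower in both for 7 of 16 genes and higher for 5 (camera adjusted p = 0.661), with -0.52 and -0.18 for DUSP6, a phosphatase that feeds back on ERK, and 0.26 and 0.24 for SPRY1, another feedback gene. The gastrointestinal lineage list was higher in both for 7 and lower for 6 of 20 genes (camera adjusted p = 0.882), and interferon-stimulated genes for 5 and 9 of 26 (camera adjusted p = 0.579). Histone and nuclear transcripts, taken as a sign of RNA quality, were higher in both libraries for 7 of 14 genes and lower for 2 (camera adjusted p = 0.144). Their medians of 0.32 and 0.17 lay at percentiles 100 and 99.9 among random lists. These medians were thus above the control, as those of the called lists were. The 18 tested lists not described here had camera adjusted p-values from 0.101 to 0.993. Markers of fibroblasts, blood cells and endothelium had 3, 4 and 2 measured genes, and enteroendocrine and neuroendocrine genes had 2, so these lists were not tested.

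**Figure D3:**
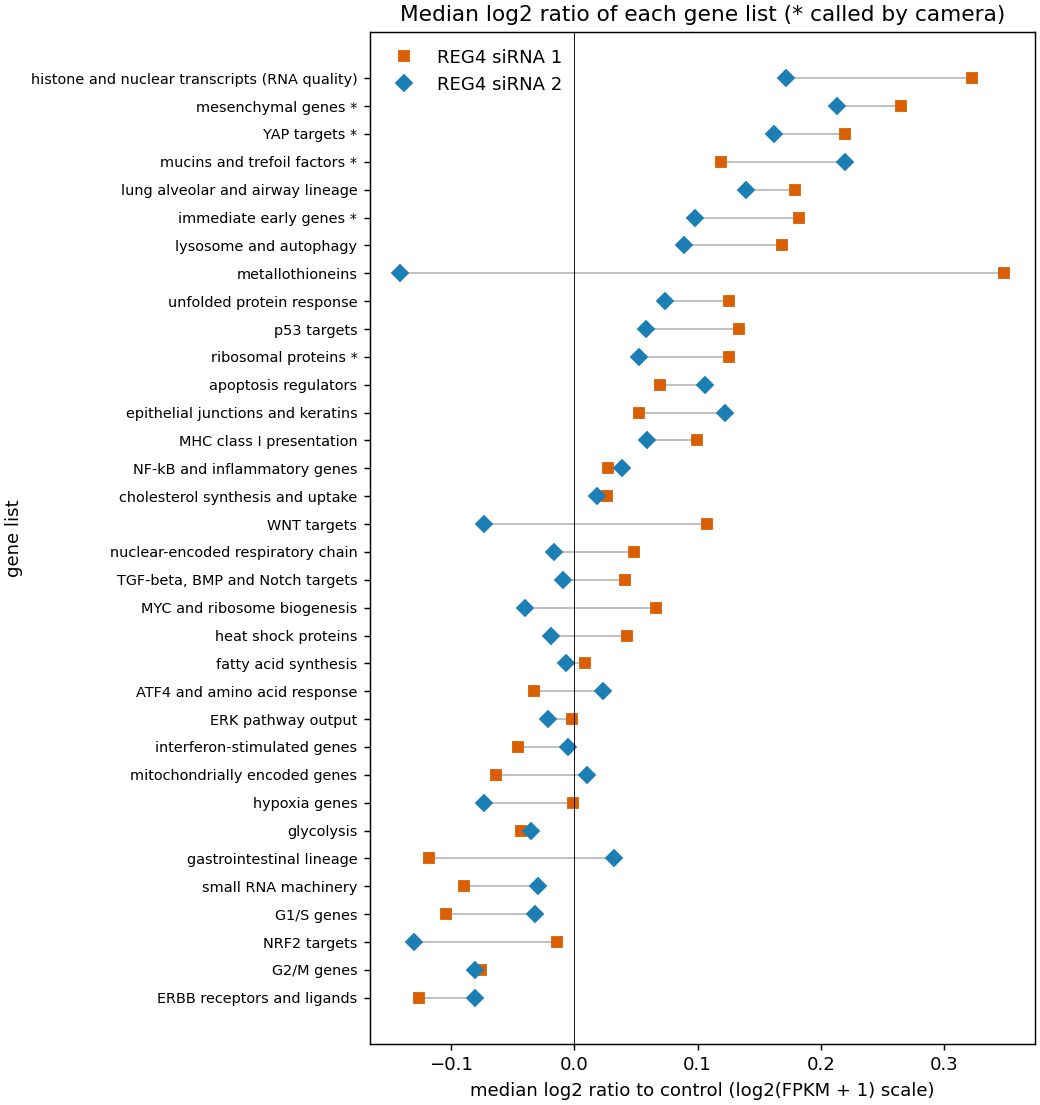
Median log2 ratio to the control (x axis, log2(FPKM + 1) scale) of each of the 34 gene lists with at least 5 measured genes (y axis) in REG4 siRNA library 1 (orange squares) and library 2 (blue diamonds), with an asterisk for the 5 lists called by camera with a preset correlation. The metallothioneins lie on opposite sides of 0, at 0.35 and -0.14, while the called lists lie above 0 in both libraries.

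The log2 ratios also followed the GC content of the genes. Among genes with at least 100 reads, GC content was known for 95.6%, and Spearman's rho across genes between GC content and the log2 ratio was 0.518 in library 1 and 0.437 in library 2. From the lowest to the highest of 10 equal classes of GC content, the median log2 ratio went from -0.16 to 0.20 in library 1 and from -0.10 to 0.13 in library 2. After a loess correction for GC content of these genes, chosen after the data were seen, limma called 2 of the 5 genes called at the read minimum, DKK4 and GAGE12E. The mean log2 ratios and standard errors of the other 3 stayed close, at 1.01 (0.13) before and 0.96 (0.12) after for ATOH1, 0.79 (0.10) and 0.78 (0.10) for TPM4, and -1.56 (0.14) and -1.53 (0.15) for SNORD16. Limma's prior degrees of freedom went from 8.65 to 6.29, which raises p-values at the same ratio and error (limma adjusted p = 0.181, 0.181 and 0.0584). Log2 ratios of some genes with a high GC content fell more. MUC5B went from 1.20 and 0.70 to 1.00 and 0.57, SPDEF from 0.71 and 0.62 to 0.51 and 0.49, and FCGBP from 0.56 and 1.04 to 0.38 and 0.92. OLFM4, of lower GC content, went from 0.96 and 0.84 to 1.02 and 0.90. The voom calls were made without a GC correction.

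Among lists, camera called the same 5 at the read minimum, and also lysosome and autophagy genes and the histone and nuclear transcripts (adjusted p = 0.0321 for each, and camera adjusted p = 0.771 for all 7 with an estimated correlation). After the GC correction, immediate early genes (adjusted p = 0.0573) and lysosome and autophagy genes (adjusted p = 0.0903) were not called by camera. Their mean log2 ratios went from 0.19 ± 0.14 to 0.11 ± 0.15 (SD, n = 15 genes) and from 0.12 ± 0.14 to 0.07 ± 0.13 (SD, n = 25 genes), so these calls ended with smaller means. The other 4 lists and the histone and nuclear transcripts (adjusted p = 0.0246) were still called by camera, although ribosomal proteins were not when gene length was corrected for as well (camera adjusted p = 0.0677). With GC content alone, camera also called apoptosis regulators (adjusted p = 0.0230) and the unfolded protein response (adjusted p = 0.0230) higher, and G1/S genes (adjusted p = 0.0230), glycolysis (adjusted p = 0.0328) and NRF2 targets (adjusted p = 0.0230) lower. None of the calls after the correction held with an estimated correlation, the camera adjusted p then being 0.730 for each. This setting again rested on 1 residual degree of freedom.

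**Figure D4:**
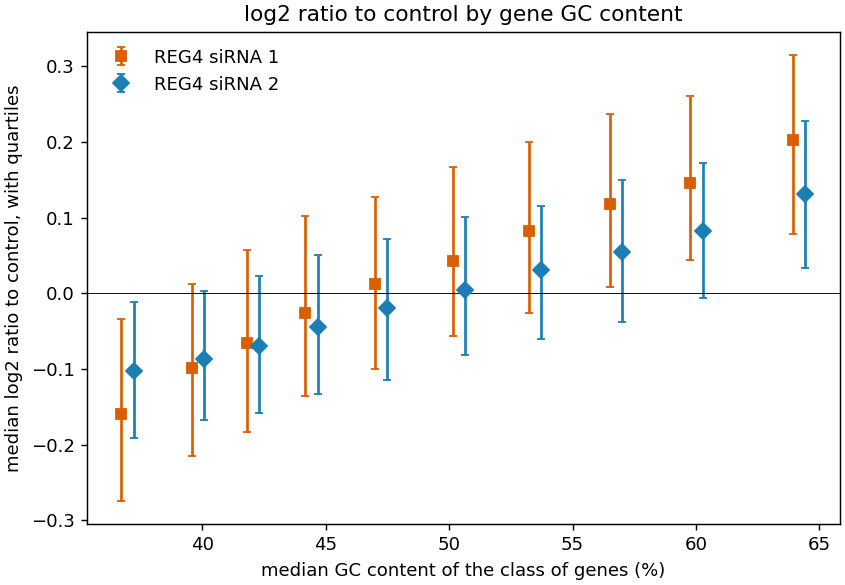
Median log2 ratio to the control (y axis, log2(FPKM + 1) scale, bars from the lower to the upper quartile) against the median GC content of each of 10 equal classes of genes (x axis, percent) in REG4 siRNA libraries 1 (orange squares) and 2 (blue diamonds), for genes with at least 100 reads. The median went from -0.16 to 0.20 in library 1 and from -0.10 to 0.13 in library 2.

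The last comparison was between the 2 REG4 siRNA libraries, which gives the spread behind the others. Among genes with at least 100 reads, RN7SK and RPPH1 differed most. RN7SK was at 58.5 FPKM in library 1 and 10.7 FPKM in library 2, and RPPH1 at 20.3 and 4.09 FPKM. RMRP (23.7 and 10.1 FPKM) and SNORD14C (36.1 and 15.8 FPKM) were also lower in library 2. The tRNA gene TRNV was higher there (61.5 and 129 FPKM). None of these is of type mRNA, and RPPH1 and RMRP belong to the histone and nuclear transcripts. The cause of these differences was not tested. The alarmin IL33 was at 25.4 FPKM in the control, 6.30 FPKM in library 1 and 21.6 FPKM in library 2, and the protease inhibitor SPINK7 was at 155, 90.6 and 232 FPKM. The adhesion molecules CEACAM5 (33.9, 18.9 and 36.3 FPKM) and CEACAM6 (23.5, 12.8 and 24.5 FPKM) and the ferritin heavy chain FTH1 (1705, 1012 and 1667 FPKM) were lower in library 1 and close to the control in library 2. The metallothioneins, which bind zinc and copper, had a median log2 ratio of 0.35 in library 1 and -0.14 in library 2, and MT1H was at 14.3, 31.2 and 8.98 FPKM. In all, 239 genes differed by at least 2-fold between the pair, of which 222 had under 100 reads, and the SD of the log2 ratio of library 2 to library 1 was 0.31 over all tested genes and 0.20 over those with at least 100 reads. This comparison holds 1 library on each side, so it has no replicate check. Across all tested genes, Pearson's r was 0.982 between the control and library 1, 0.985 between the control and library 2 and 0.984 between the pair, and the order was the same over genes with at least 100 reads. Library 1 thus stood slightly further from the control than library 2 did, although REG4 itself was lower in library 2.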

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

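The alternatives with a read minimum, voom or a GC correction were chosen after the data were seen, and the others before. Both corrections and voom used genes with at least 100 reads. REG4 stayed below the control under every alternative run, with mean log2 ratios between -1.89 and -1.80 over the settings that kept both libraries and -2.43 to -1.24 when either REG4 siRNA library was left out. Leaving out a library left 1 against 1, so limma, camera and the correlation gave no value there. No paired analysis was possible because the control has 1 library. Limma's count of 0 called genes was also 0 with pseudocounts of 0.1 and 5, median-ratio scaling, quantile normalization, no filter, no trend and an adjusted p under 0.1 as threshold (729 genes had an unadjusted p under 0.05 without trend, against 777). It was 7 with a mean FPKM of at least 5, 5 with a read minimum of 100, 21 with 300, 15 with voom, 2 with the GC correction and 0 with the correction for GC and length.

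Genes at least 2-fold in both libraries numbered 80. They were 157 with a pseudocount of 0.1, 14 with 5, 168 without a filter, 16 with a mean FPKM of at least 5, and 5 with a read minimum of 100, with the GC correction and with the correction for GC and length. A threshold of 1.5-fold gave 245 genes, 3-fold gave 21, and 1.5-fold with the read minimum gave 51, or 32 with the GC correction. Leaving out a REG4 siRNA library gave 232 to 237. The share of higher genes was 60.0% as planned, 59.3% with median-ratio scaling and 59.5% with quantile normalization, but 36.9% without a filter, 28.6% with a pseudocount of 5 and 37.5% with a mean FPKM of at least 5, and 1 gene was higher against 4 lower with a read minimum of 100. With that minimum, the share was 68.2% of 22 genes without a pseudocount and 74.5% at 1.5-fold, so the majority depended on the pseudocount, the filter and the threshold together. The difference between the pair, 239 genes, became 420 and 43 with pseudocounts of 0.1 and 5, 431 without a filter, 71 with a mean FPKM of at least 5, 17 with the read minimum, with and without either correction, and 660 at 1.5-fold. Of the 24 genes selected by the naming rule, 9 were selected with a pseudocount of 5, 2 with the read minimum and with either correction, and 9 when either library was left out.

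The correlation of the log2 ratios was 0.536 with a pseudocount of 5, 0.590 with a read minimum of 100 and 0.613 with 300, but 0.504 with the GC correction and 0.506 with the correction for GC and length. Simulated unchanged libraries sharing a control gave 0.499 at the read minimum of 100 (95% of draws between 0.486 and 0.514). The simulation gave every library the same spread and no GC trend. A control that varied more than the REG4 siRNA libraries may thus also give a higher correlation, so this difference is no sign of a shared response. Camera called 5 lists, 1 with a mean FPKM of at least 5, 10 with the GC correction, 8 with the correction for GC and length, and 0 with an estimated correlation. Without a filter, camera did not call mesenchymal genes (adjusted p = 0.445), mucins and trefoil factors or YAP targets (adjusted p = 0.0547 for each). With a mean FPKM of at least 5, only ribosomal proteins stayed called. Camera did not call these with quantile normalization (adjusted p = 0.0633) or the correction for GC and length (adjusted p = 0.0677), YAP targets with a pseudocount of 5 (adjusted p = 0.0566), mesenchymal genes with a read minimum of 300 (adjusted p = 0.0661), or immediate early genes with either correction. The cause of these differences was not tested. Low read numbers limit the small RNA genes, and the lone control library limits every comparison with the control.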

Other observations

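The lists of goblet and Paneth cell, enterocyte and stem cell genes below, and the tests of a trend in the difference between the REG4 siRNA libraries, of depth, of genes not of type mRNA, of the goblet and Paneth cell list with camera, of a graded response and of other groupings of the libraries, were chosen after the results were seen. Among 34 goblet and Paneth cell genes with at least 100 reads, 25 were higher in both REG4 siRNA libraries and 3 were lower. Their median log2 ratios were 0.55 and 0.46. After the GC correction 24 were higher and 3 lower, with medians of 0.44 and 0.41. The ratios of single genes that follow are without the correction. Besides the genes named above, the goblet cell factors FOXA3 (0.64 and 0.39) and CREB3L1 (0.61 and 0.40), the Notch ligands DLL1 (0.58 and 0.53) and DLL4 (0.45 and 0.59), SPINK4 (0.79 and 0.62) and the sialyltransferase ST6GALNAC1 (0.66 and 0.38) were higher. The list was not uniform, since lysozyme, LYZ, was lower (-0.69 and -0.47), MUC2, the main intestinal mucin, had -0.06 and 0.27, and ITLN1 (1.18 and -0.34) and PLA2G2A (0.54 and -0.26) differed in sign. The Paneth cell defensins DEFA5 and DEFA6 (1.49 and 0.74) were higher in both libraries, so genes of Paneth cells went both ways. Among 13 genes of absorptive enterocytes, 4 were higher in both libraries and 3 lower, with medians of -0.01 and 0.04, and among 16 intestinal stem cell genes 6 were higher and 4 lower, with medians of 0.08 and 0.00.

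One hypothesis is that the list of goblet and Paneth cell genes moved beyond a few selected genes. The 20 members outside the genes with the largest changes had medians of 0.21 and 0.21 after the GC correction, at percentile 100 among random lists in both libraries, and 11 of them were higher in both libraries and 2 lower. Random lists ignore correlation between genes, and camera gave p = 0.000107 for these members with the preset correlation but p = 0.148 with an estimated correlation. The estimated correlation was -0.053, so the larger p came from the 1 residual degree of freedom used with it and decides nothing. That estimate depends only on how many members were higher in library 2 than in library 1, so it cannot exclude correlation between genes. Since the list was assembled after secretory genes were seen to be higher, the hypothesis stays open. For the mucins and trefoil factors fixed in advance, the smaller percentile, that of library 1, was 79.8 at the read minimum, within the range of random lists, and 97.8 after the GC correction. This passed the limit written beforehand. The margin was narrow, and a wider one, considered after the value was seen, would have left the question open. The medians at the read minimum, 0.09 and 0.24, were 0.11 and 0.25 after the correction, while the mean over its genes went from 0.29 to 0.22. In library 2 the percentile was 100 before and after, which argues against GC content as the whole explanation there. In library 1 the uncorrected list did not stand out, so little was left to explain. Camera on ranked log2 ratios called the list at the read minimum but not after the correction, while camera on the values called it both times. Both libraries share the same control, so a control library that happened to be low in secretory genes may give the same picture and was not tested.

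The rise of the log2 ratios with GC content may be a property of single libraries, since the log2 ratio of REG4 siRNA library 2 to library 1 also followed GC content (Spearman's rho = -0.218). The read totals of libraries 1 and 2 lie below and above that of the control, while both rhos were above 0, the smaller being 0.437, which argues against depth. Thinning to equal totals changed too few reads to test this. GC content was known for 652 genes not of type mRNA. Their rhos were 0.208 (95% bootstrap interval 0.137 to 0.284) and 0.193 (0.117 to 0.267). These were above 0 but smaller than over all genes with at least 100 reads (0.518 and 0.437). Such types include copies of coding genes, such as RPL13AP25, that could share reads with them. A trend limited to protein-coding genes is thus not excluded. The bound of 0.2 set before the result was met in library 1 only, so the interval was used instead. For 411 further genes of such types GC content was not known. After the GC correction the covariance of the log2 ratios was 0.0182, against 0.0185 for the variance of the difference between the pair divided by 2, where it had been 0.0273 against 0.0200. A response of GC-rich genes to the siRNA cannot be told apart from a GC bias of the control library, because the design has 1 control.

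REG4 was lower in library 2 than in library 1, so a graded response of other genes was looked for. Of 31 genes changed at least 1.5-fold the same way in both libraries after the GC correction, 48.4% changed more in library 2 (exact 95% interval 30.2 to 66.9), which neither shows nor excludes a graded response. The 3 libraries allow 3 groupings of 1 against 2, too few for a share under 0.05. With a read minimum of 100, limma called 5 genes when the control stood alone, 180 when REG4 siRNA library 1 stood alone and 6 when library 2 did, and all 3 groupings thus gave as many as the real one. After the GC correction these counts were 2, 38 and 0, and without the read minimum they were 0, 0 and 1.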
